A study of Mus musculus with 24 samples.

How the data were processed

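The series holds 24 single-channel Affymetrix arrays of 4T1 cells, 3 for each of 8 groups, mapped to groups by their titles. Total RNA was purified on RNeasy columns and biotin-labelled cRNA was hybridised, per the labels' protocols. The deposited values are the authors' log2 signals from RMA in Affymetrix Expression Console 1.1, per the submitters' processing notes; the base of the logarithm is not written in the table and was inferred from the range of values (0.96 to 14.71). The settings of background correction, quantile normalisation and summary are not given in the sources used here, and no raw images were processed. Array medians lay between 4.40 and 4.75. The median over genes of the SD between replicates was 0.198.

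The table held 35557 probe sets. An annotation table of 23410 probe sets, dated 2016, gave 1 gene symbol for 21789 of them and several for 1621, and 12147 had none. Each gene was represented by the probe set with 1 symbol and the highest mean over the 24 arrays, which left 19938 genes, 999 of them with more than 1 probe set. Probe sets with several symbols or none were left out of gene counts.

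Group means were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3 on all 24 arrays with 16 residual degrees of freedom. Each treated day was compared with control and each sampled day with the one before it. An F test asked for differences between the 7 treated days, and a slope per day was fitted to the 21 treated arrays. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p below 0.05. Errors are standard errors (SE) of the fit for changes and standard deviations (SD) of 3 arrays for means. The replicates carry the same numbers in each group, but replicates with the same number did not resemble each other across groups, so they were not paired. The labels do not say whether replicates came from separate cultures, and p-values measure the spread between these arrays.

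Before the data were examined, 30 gene lists with 599 memberships were fixed, of which 556 were measured. They were tested on each day against control with camera (limma), with a preset correlation between genes of 0.01, and p-values were adjusted over 210 tests. The same test was run with the correlation estimated for each list. The number of members past the threshold is given over all genes and, where it says so, adjusted over the list alone. Expected overlaps of called genes are those of independent lists. Simulated groups without change that shared their controls gave the correlation that shared controls make when all groups have the same spread. Another 8 gene families were chosen after the data were seen and tested the same way, adjusted over 56 tests.

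Genes were chosen for naming by rule: the 10 largest rises and 10 largest falls past the threshold on days 1 and 11, with all 3 arrays of the day on one side of all 3 control arrays, a separation that 1 in 10 genes would show by chance in either direction, 3 and 3 on other days, 2 and 2 for each step, 5 and 5 for the trend, 5 and 5 with the same sign on all 7 days, and up to 2 rises and 2 falls of each list. A set of 17 genes of lactate and glucose use, growth and survival was reported whatever its values. Predicted genes, genes of the Y chromosome and Xist were not named. Lbp, Il24, Cdh17, Cp and Lcn2 as opposite pairs, and members of the families, were chosen after their values had been seen.

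The procedure was tested on simulated data with 1 spread per gene, taken from the fit and equal in all groups. It recovered 23.0% of 1.41-fold, 84.5% of 2-fold and 100% of 4-fold changes on day 1, and 27.4%, 86.9% and 100% on day 11. False calls numbered 5 and 4 over 19938 genes. The simulated genes were independent and no simulated array stood apart, so these rates may not hold for the real day 1.

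Alternatives were the mean of all probe sets of a gene, every probe set tested, omission of the 40% dimmest genes, cyclic loess between arrays, median centring of arrays, a mean trend with robust variances, array weights, a replicate block, omission of each array of the groups compared in turn, only the 6 arrays compared, only the 21 treated arrays, an adjusted p below 0.01, a 2-fold minimum, log2 of the day, a trend without day 1, an estimated correlation and the fry test for lists. Omission of day 1 replicate 1 and day 9 replicates 2 and 3, named below the 3 arrays that stood apart, was added after the data were seen. So was omission of day 1 replicate 1 alone from every fit. These 3 arrays had the highest medians, but only day 1 replicate 1 lay outside the others in SD across genes. Other splits of the arrays into groups were computed for each comparison. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.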

Results

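RNA from the mouse mammary carcinoma line 4T1 was measured on 24 Affymetrix arrays. Control cells grew with 3 mM glucose and no added lactic acid, and treated cells grew with 3 mM glucose and 20 mM lactic acid and were collected on days 1, 3, 4, 5, 7, 9 and 11. The study set out to learn which genes change over time while lactic acid keeps glucose-starved tumour cells alive for longer. Each of the 8 groups had 3 arrays, labelled as biological replicates, and their number limits the precision. The labels do not state how long the control cells were cultured, so each comparison with control contains both lactic acid and time in culture. Values of 19938 genes are given on the log2 scale, and the range of the table (0.96 to 14.71) is the ground for reading them as log2.

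On day 1 Txnip and several chemokine genes lay below control and Cpt1a lay above it. Txnip, which restrains glucose uptake and responds to glucose supply, fell by 2.47 on the log2 scale (SE 0.21, 5.55-fold, adjusted p = 3.00e-07), from a control mean of 8.05 (SD 0.47, n = 3) to 5.58 (SD 0.58, n = 3). The chemokine genes Cxcl5 (-2.93, SE 0.29), Ccl20 (-2.06, SE 0.27), Ccl2 (-1.74) and Ccl5 (-1.71, SE 0.12, adjusted p = 3.73e-09) fell, as did the acute-phase genes Cp (-2.43, SE 0.19) and Lcn2 (-1.67, SE 0.18) and the glycoprotein gene Gpnmb (-2.08). Cpt1a, whose product carries fatty acids into mitochondria, rose by 1.59 (SE 0.15, 3.02-fold, adjusted p = 1.04e-06), from 6.86 (SD 0.14) to 8.46 (SD 0.31). AU018091 rose by 3.05 (SE 0.14, 8.28-fold, adjusted p = 2.98e-12), and the hyaluronan synthase gene Has2 (1.76, SE 0.20), Cdh17 (1.75), Il1a (1.74), Arhgap42 (1.58), Slco5a1 (1.53) and Serpinb2 (1.42) rose as well. Usp17ld (-3.87, SE 0.51), AY036118 (-2.52), Prl2c5 (1.33) and the receptor gene Olfr767 (1.97, SE 0.44) also passed, but they belong to families with near-identical copies, so which copy changed is uncertain. All 3 day 1 arrays lay on one side of all 3 control arrays for each of these genes, which was a condition for naming them.

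Day 1 differed from control in 960 of 19938 genes (4.81%), 458 higher and 502 lower, of which 79 changed at least 2-fold (limma, adjusted p below 0.05, n = 3 and 3). The balance turned with arrays centred on their medians (499 higher, 303 lower), after cyclic loess (798 and 730) and without the 3 arrays that stood apart (933 and 611). The count was 6 with only the 6 arrays compared (1863 at an unadjusted p under 0.05), 1528 after cyclic loess and 8640 with array weights. Without control replicate 1, 2 or 3 the count was 421, 411 or 519, and without day 1 replicate 1, 2 or 3 it was 916, 3026 or 1453. Day 1 replicate 1 stood apart from the other arrays, with an SD across genes of 1.94 against 2.16 to 2.34 for 21 others and a median correlation with its own group of 0.943. The call of Olfr767 was lost without control replicate 1 (adjusted p = 0.0621).

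Among the gene lists fixed beforehand, the inflammatory cytokine and NF-kB list lay lower on day 1: of 22 genes 7 fell, 1 rose (Il1a) and 14 did not pass, with Cxcl5 and Ccl20 the largest falls (adjusted p = 0.0018, and adjusted p = 0.196 with an estimated correlation). Adjusted over the list alone, 9 fell and 5 rose. Fatty acid oxidation genes lay higher (5 rose, 1 fell, 12 not passed, over the list alone 8 and 3), with Cpt1a and Ech1 (0.69) rising and Eci1 (-0.36) falling (adjusted p = 0.0013, and adjusted p = 0.129 with an estimated correlation). HIF-1 targets lay higher (5 rose, 0 fell, 15 not passed, over the list alone 8 and 0), with Ankrd37 at 0.91 and Adm at 0.79 (adjusted p = 2.93e-04, and adjusted p = 0.150 with an estimated correlation). Cholesterol synthesis and uptake genes lay lower (5 fell, 15 not passed, over the list alone 8 fell), with Hmgcs1 at -0.88 and Insig1 at -0.87 (adjusted p = 3.01e-08, and adjusted p = 0.189 with an estimated correlation). ATF4 targets lay lower (4 fell, 24 not passed; Cth -1.24, Chac1 -1.16, adjusted p = 1.47e-06, and adjusted p = 0.212 with an estimated correlation). Lysosome genes (7 fell, 16 not passed, over the list alone 8 and 1 higher; Lamp2 -0.89, Ctsb -0.72, adjusted p = 5.45e-05, and adjusted p = 0.196 with an estimated correlation) lay lower. Interferon response genes lay lower as well, Ccl5 and Cxcl10 (-0.83) most (5 fell, 20 not passed, over the list alone 7 fell, adjusted p = 8.11e-05, and adjusted p = 0.146 with an estimated correlation). Mitosis genes lay lower with 1 of 27 past the threshold (Nusap1 -0.77, over the list alone 5; adjusted p = 6.15e-10, and adjusted p = 0.254 with an estimated correlation). In all, 16 of 30 lists were called on day 1 with the preset correlation and 0 with an estimated one (camera). After cyclic loess, without day 1 replicate 1 and without the 3 arrays that stood apart, 9 of the 16 were still called each time, all those named in this paragraph among them. That array carried much of the change in some of them. The mean change of mitosis genes was -1.06 in day 1 replicate 1 against -0.10 and -0.25 in replicates 2 and 3, that of cholesterol genes -0.68 against -0.22 and -0.28, and that of lysosome genes -0.43 against -0.13 and -0.12. Marker lists of cells other than tumour cells lay higher in day 1 replicate 1 (leukocytes 0.45, endothelium 0.42, adipocytes 0.40, fibroblasts 0.29). In replicates 2 and 3 they lay between -0.26 and 0.12. Control replicate 1 lay apart in ATF4 targets (0.33, other controls -0.17 and -0.16) and in cholesterol genes (-0.28, other controls 0.14 and 0.15), and in the latter neither day 1 replicate 2 nor 3 lay below it. Without it the mean change of ATF4 targets went from -0.30 to -0.13 (adjusted p = 0.0073) and that of cholesterol genes from -0.39 to -0.54 (adjusted p = 2.87e-14).

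From day 3 on, cell division and sterol synthesis genes lay below control while most endoplasmic reticulum chaperone genes and many interferon response genes lay above it. On day 3 the thymidine kinase gene Tk1 fell by 3.10 (SE 0.16, adjusted p = 1.88e-12), from 9.72 (SD 0.06) to 6.62 (SD 0.19), and Plk1, a mitotic kinase gene, fell by 2.97 (SE 0.19). Tnnc1, a troponin gene of slow and cardiac muscle, rose by 4.01 (SE 0.22, 16.1-fold, adjusted p = 8.65e-12), the chaperone gene Dnajb9 by 3.36 (SE 0.37) and the secreted protease inhibitor gene Fetub by 3.34 (SE 0.18). Day 4 brought Fetub to 4.70, Tnnc1 to 4.43 and the matrix gene Ogn to 4.08 above control (SE 0.18, 0.22 and 0.23), with Plk1 at -4.04 and Hmmr at -3.86. On day 5 Fetub (4.19, SE 0.18, adjusted p = 2.33e-13), Tnnc1 (4.04) and Lbp (3.95) led the rises and the lipid carrier gene Fabp5 fell by 2.99 (SE 0.20, adjusted p = 1.69e-10). Day 7 had Fetub at 5.47 (44.5-fold), Lbp at 4.33 and Rtp4 at 4.21, against Ccna2 at -4.25. By day 9 came Fetub at 5.65 (50.1-fold), Ogn at 4.76 and Lbp at 4.48, against Ccna2 at -5.22, Kif20a at -4.89 and Hmmr at -4.78. The histone genes H2ac4 (-4.01 on day 3, -4.36 on day 4, -3.66 on day 5, -4.53 on day 7) and H1f5 (-3.15 on day 5, -4.44 on day 7) fell too. H2ac4 belongs to a multi-copy family, so the copy is uncertain.

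All 27 mitosis genes fell on days 3, 4 and 5, with medians of -1.94 (adjusted p = 4.96e-31), -3.03 (adjusted p = 9.01e-40) and -1.99 (adjusted p = 7.84e-34). DNA replication genes fell in 29 of 29 cases on day 3 (median -1.57; Tk1 -3.10, Rrm2 -2.89, adjusted p = 3.96e-31) and in 28 of 29 on day 5 (median -1.47, adjusted p = 7.04e-30). Cholesterol synthesis and uptake genes fell in 19 of 20 cases on day 3 (median -1.12; Idi1 -2.66, Cyp51 -2.02, adjusted p = 7.87e-18, and adjusted p = 0.0412 with an estimated correlation). On day 5 they fell in 19 of 20 cases too, but that call was lost with an estimated correlation (median -0.96, camera, adjusted p = 1.42e-13 and 0.0968). Endoplasmic reticulum chaperones rose in 17 of 19 cases on day 3 (median 1.27; Dnajb9, and Creld2 2.12, adjusted p = 2.15e-13, and adjusted p = 0.165 with an estimated correlation). Interferon response genes stood at 13 higher, 1 lower and 11 not passed on day 3 (over the list alone 15 and 2, Rtp4 2.71, Irf9 1.48, Ccl5 -0.42, adjusted p = 8.91e-06, and adjusted p = 0.114 with an estimated correlation). On day 5 they stood at 19 higher and 6 not passed (Rtp4 2.72, Irf7 2.57, adjusted p = 4.69e-14). Ribosome biogenesis and MYC genes fell in 16 of 22 cases on day 3 (median -0.81; Bop1 -1.83, Bysl -1.70, adjusted p = 9.80e-12, and adjusted p = 0.107 with an estimated correlation). Respiratory chain and ATP synthase genes stood at 2 higher, 29 lower and 11 not passed on day 3 (Uqcrc1 -1.60, Cyc1 -1.50, adjusted p = 1.70e-13, and adjusted p = 0.0968 with an estimated correlation). The epithelial list was called on day 5 only (11 rose, 1 fell; Cldn4 2.35, Jup 1.56; Krt19 -0.69, adjusted p = 0.0235, and adjusted p = 0.275 with an estimated correlation), and its adjusted p was 0.0513 without day 1 replicate 1.

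The number of genes past the threshold was 5239 on day 3 (2477 higher, 2762 lower), 5369 on day 4 (2799 and 2570), 5477 on day 5 (3422 and 2055), 5074 on day 7 (3192 and 1882) and 5414 on day 9 (2621 and 2793, limma, n = 3 and 3 each). With arrays centred on their medians day 3 had 1762 higher and 3069 lower, and after cyclic loess day 5 had 3102 higher and 2885 lower and day 7 2914 and 2544. Without the 3 arrays that stood apart day 3 had 3732 higher and 3584 lower. The balance of day 9 turned as well, with 2883 higher and 2351 lower with arrays centred and 3224 and 2959 after cyclic loess.

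**Figure D1:**
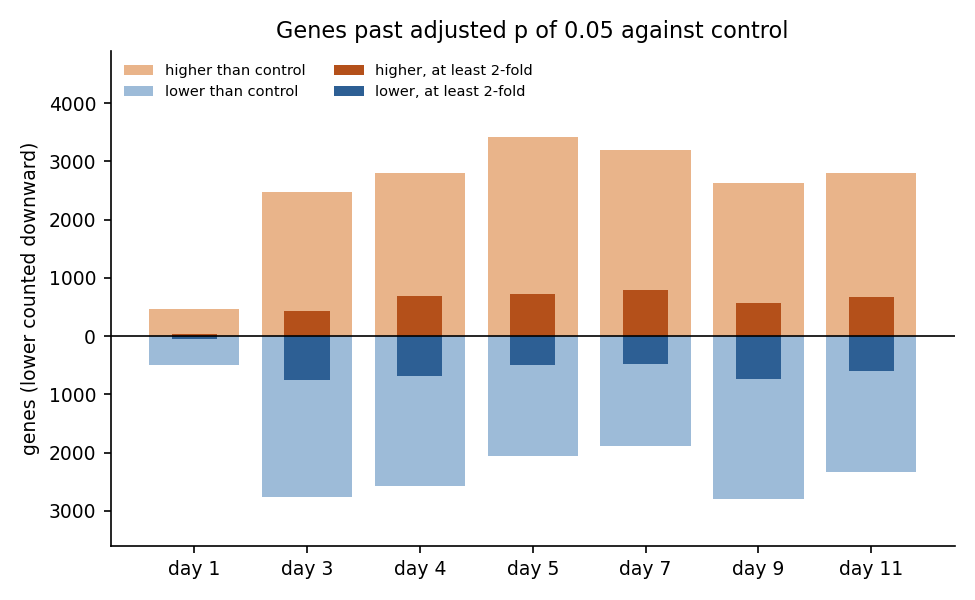
Genes past the threshold on each treated day against control (x, day; y, number of genes, higher upward and lower downward), the dark part of each bar being those that changed at least 2-fold, n = 3 arrays a group. Day 1 had 960 genes and day 3 had 5239.

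On day 11, when treated cells had spent longest with lactic acid, mitotic genes lay far below control, and Fetub, Lbp and interferon response genes such as Rtp4 lay far above it. Fetub rose by 6.56 (SE 0.18, 94.5-fold, adjusted p = 3.65e-17), from 4.00 (SD 0.19, n = 3) in control to 10.56 (SD 0.12, n = 3). The genes of the lipopolysaccharide-binding protein Lbp (4.69, SE 0.18, 25.8-fold), Ogn (4.43, SE 0.23), the interferon-induced chaperone Rtp4 (4.35, SE 0.13, adjusted p = 1.13e-16), Dnajb9 (4.21, SE 0.37), Tnnc1 (3.80, SE 0.22), the stress gene Trp53inp1 (3.73), the guanylate-binding gene Gbp4 (3.69), the thioesterase gene Acot2 (3.46) and the ferroxidase gene Cp (3.39, SE 0.19, 10.5-fold) followed. Control means of Fetub, Rtp4 (3.77) and Ogn (3.17) lay below the medians of the control arrays (4.46 to 4.55), so the size of their folds is uncertain. Ccna2, the cyclin gene of S phase and G2, fell by 5.00 (SE 0.25, 32.0-fold, adjusted p = 3.71e-13), from 10.13 (SD 0.08) to 5.13 (SD 0.21), and the proliferation marker gene Mki67 fell by 4.69 (SE 0.21, 25.8-fold). Plk1 (-4.88, SE 0.19), Kif20a (-4.84), Ccnb2 (-4.54), Kif2c (-4.53), Hmmr (-4.52), Kif11 (-4.45), Pclaf (-4.39) and H2ac4 (-4.39) fell as well. All 3 day 11 arrays lay on one side of all 3 control arrays for each gene, again a condition for naming it. Day 11 differed from control in 5143 of 19938 genes (25.8%), 2800 higher and 2343 lower, with 677 higher and 608 lower by at least 2-fold (limma, n = 3 and 3).

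**Figure D2:**
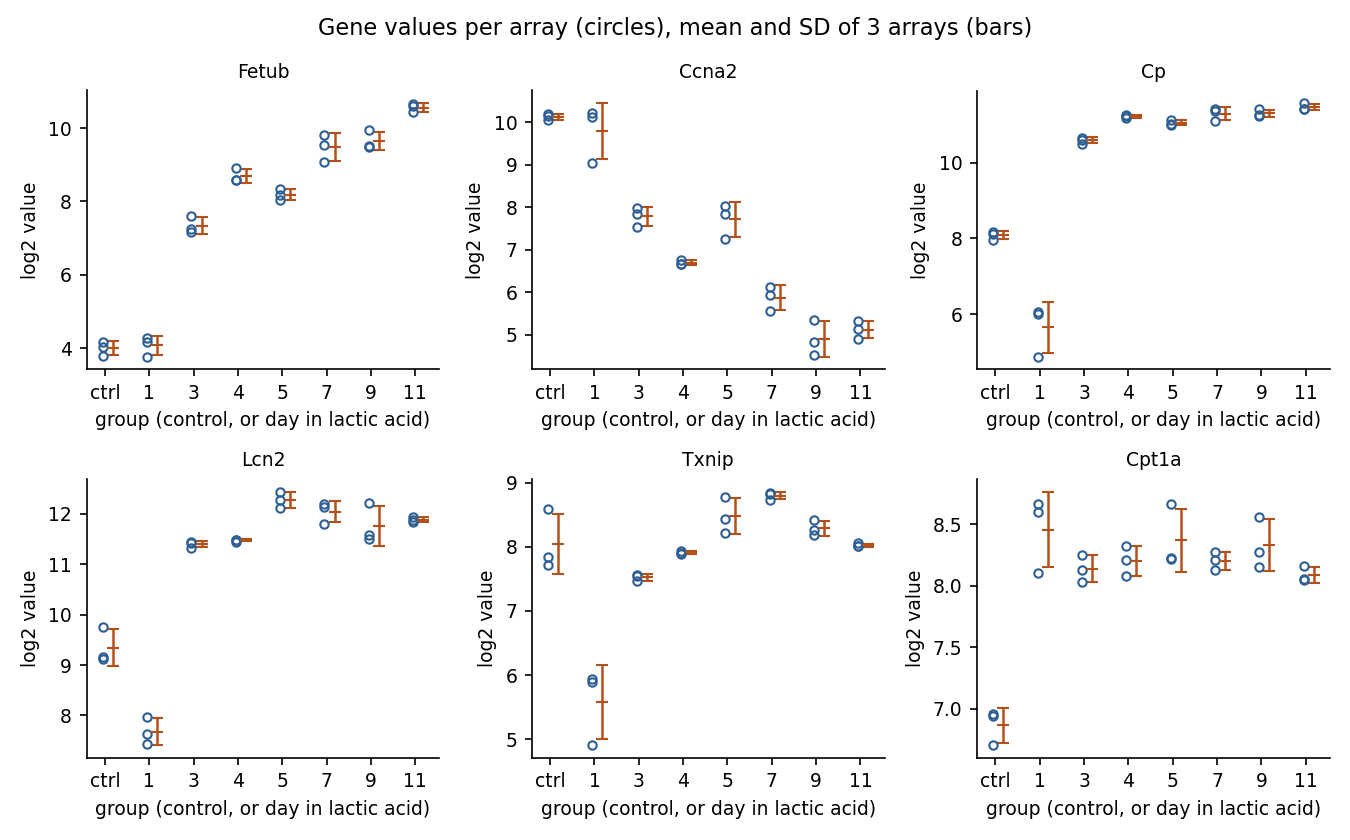
Values of Fetub, Ccna2, Cp, Lcn2, Txnip and Cpt1a (y, log2 value; x, control and treated days), circles being arrays and bars the mean and SD of 3 arrays. Cp lay at 5.65 on day 1, below the control mean of 8.08, and at 11.47 on day 11.

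Every member of the mitosis list (27 of 27, median -3.62, adjusted p = 5.58e-47) and of the DNA replication list (29 of 29, median -2.07; Rrm2 -3.82, Tk1 -3.80, adjusted p = 6.38e-37) fell on day 11. Cholesterol synthesis and uptake genes fell in 20 of 20 cases (median -1.38, Idi1 -3.15, Fdps -2.09, adjusted p = 5.00e-20). Fatty acid synthesis genes fell in 11 of 12 (median -1.02; Fads2 -2.22, Scd2 -2.06, adjusted p = 7.59e-11, and adjusted p = 0.118 with an estimated correlation). Interferon response genes stood at 16 higher, 2 lower and 7 not passed (median 1.51; Rtp4 4.35, Usp18 2.57; Ccl5 -1.52, Cxcl10 -0.71, adjusted p = 1.11e-12). The endoplasmic reticulum chaperones rose in 18 of 19 cases (median 1.05; Dnajb9, and Hyou1 2.13, adjusted p = 8.22e-14, and adjusted p = 0.155 with an estimated correlation). The 4 calls given here without a second p, mitosis, DNA replication, cholesterol and interferon, held with an estimated correlation (adjusted p = 0.0148, 0.0142, 0.0334 and 0.0142).

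**Figure D3:**
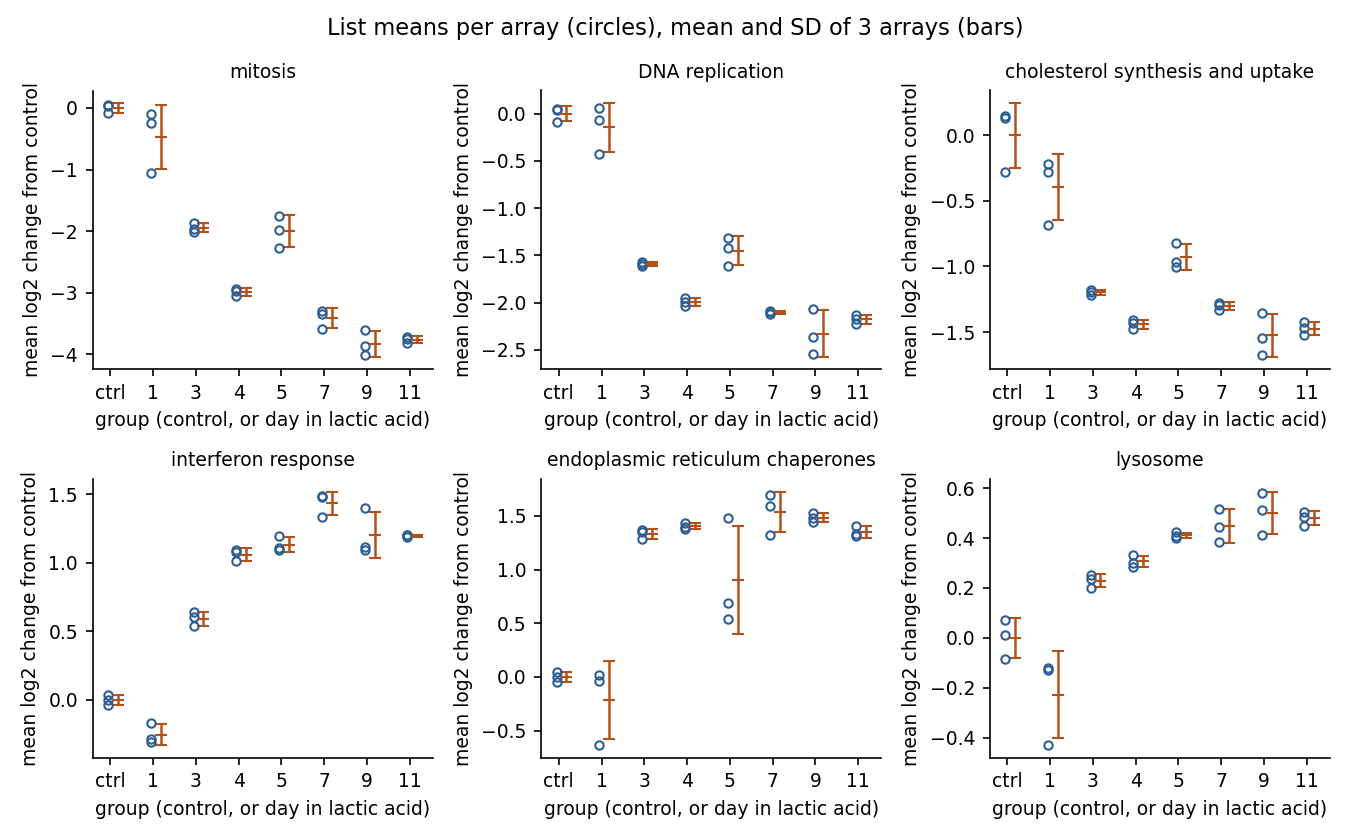
Mean log2 change from control of the measured genes of 6 lists (y) on each treated day (x), circles being arrays and bars the mean and SD of 3 arrays. Mitosis, DNA replication and cholesterol genes lay below 0 and interferon, endoplasmic reticulum chaperone and lysosome genes above 0 on day 11.

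Lists of recycling, stress and fuel use genes had smaller medians on day 11, from 0.21 (p53 targets) to 0.61 (lysosome), although single members moved far more. Of 20 autophagy genes 12 rose, 1 fell and 7 did not pass (over the list alone 12 and 2; Gabarapl1 1.27, Sqstm1 1.22; Atg7 -0.35, adjusted p = 4.66e-05, and adjusted p = 0.214 with an estimated correlation). Of 23 lysosome genes 14 rose, 2 fell and 7 did not pass (over the list alone 15 and 3; Scarb2 2.09, Lamp2 1.45; Gusb -1.99, Gla -0.37, adjusted p = 1.27e-05, and adjusted p = 0.177 with an estimated correlation). FoxO and MondoA targets rose in 9 of 20 cases with 11 not passed (over the list alone 12 rose; Bcl6 2.28, Insr 1.65, adjusted p = 2.64e-06, and 0.0142 with an estimated correlation). ATF4 targets stood at 13 higher, 3 lower and 12 not passed (over the list alone 16 and 4; Slc7a11 2.86, Ddit3 2.51; Shmt2 -1.09, Psat1 -0.87, adjusted p = 3.88e-04, and adjusted p = 0.367 with an estimated correlation). For p53 targets 7 rose and 9 did not pass (Trp53inp1, and Gadd45a 2.76, adjusted p = 0.0146, and adjusted p = 0.123 with an estimated correlation). Cdkn1a and Bax, also fixed in that list, were not tested, and the activity of p53 was not measured. For fatty acid oxidation 8 rose and 10 did not pass (over the list alone 8 and 1; Cpt1a 1.22, Etfdh 1.02, adjusted p = 0.0105, and adjusted p = 0.196 with an estimated correlation).

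The glycolysis, TCA cycle, respiratory chain and ribosome biogenesis lists lay lower on day 11. Glycolysis genes fell in 8 of 16 cases with 8 not passed (Pgam1 -1.41, Ldha -1.12, adjusted p = 6.90e-04, and adjusted p = 0.212 with an estimated correlation). TCA cycle and pyruvate dehydrogenase genes fell in 13 of 20 cases with 7 not passed (over the list alone 15; Sdhd -1.07, Cs -0.95, adjusted p = 2.51e-05, and adjusted p = 0.201 with an estimated correlation). Respiratory chain and ATP synthase genes stood at 4 higher, 23 lower and 15 not passed (over the list alone 4 and 24; Ndufa2 0.64, Ndufb10 0.61; Uqcrc1 -1.48, Cox7b -1.09, adjusted p = 8.97e-06, and adjusted p = 0.276 with an estimated correlation). Ribosome biogenesis and MYC genes stood at 1 higher (Myc 0.55), 10 lower and 11 not passed (over the list alone 3 and 12; Bop1 -1.31, Polr1b -1.02, adjusted p = 0.0117, and adjusted p = 0.523 with an estimated correlation). On day 11, 16 of 30 lists were called, 5 of them with an estimated correlation (camera, n = 3 and 3). All 16 were called after cyclic loess, with arrays centred on their medians and without the 3 arrays that stood apart, whereas on day 7 cyclic loess kept 13 of 17 calls.

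Lists that were not called on day 11 held single genes that changed. Lactate and pyruvate use and gluconeogenesis had 1 higher and 1 lower of 14 (Me1 0.97, Me2 -1.30, adjusted p = 0.621). The pH regulation and proton sensing list had 1 lower of 12 (Car12 -0.78, adjusted p = 0.218). HIF-1 targets had 5 higher and 2 lower of 20 (Vegfa 1.60, Ddit4 1.26; Car12, adjusted p = 0.231). NRF2 targets and pentose phosphate pathway genes had 4 higher and 4 lower of 18 (Gstm1 1.16, Pgd -1.01, adjusted p = 0.424). AMPK subunits and mTORC1 regulators had 5 higher and 2 lower of 16 (Rheb 1.07, Castor1 -1.11, adjusted p = 0.168). The anti-apoptotic list had 4 higher of 8 (Cflar 1.62, Birc2 1.27, adjusted p = 0.0682, and 0.0415 without the 3 arrays that stood apart). The pro-apoptotic and caspase list had 1 higher and 4 lower of 15 (Bcl2l11 0.77; Bok -1.17, Bak1 -1.10, adjusted p = 0.122). Inflammatory cytokines had 2 higher and 6 lower of 22 (Lcn2 2.54, Csf1 0.92; Ccl2 -1.68, Ccl20 -1.38, adjusted p = 0.585). Mesenchymal and matrix genes had 4 higher and 3 lower of 22 (Fn1 2.46, Thbs1 1.75; Mmp3 -3.11, Vim -1.18, adjusted p = 0.960). Epithelial genes had 4 higher and 2 lower of 21 (Cldn4 1.73, Krt19 -0.66, adjusted p = 0.621). Marker lists of cells other than tumour cells were not called on day 11: leukocytes (0 of 9, adjusted p = 0.742), fibroblasts (2 higher of 9, Pdgfra 1.79 and Pdgfrb 1.32, adjusted p = 0.171), endothelium (0 of 7, adjusted p = 0.789) and adipocytes (0 of 6, adjusted p = 0.832). On day 3 the fibroblast list was called, with 3 higher of 9 (Pdgfra 2.42, Pdgfrb 1.05, adjusted p = 0.0343, and adjusted p = 0.332 with an estimated correlation), and its adjusted p was 0.0659 after cyclic loess and 0.0618 without day 1 replicate 1.

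Among genes of lactate, glucose and survival fixed for reporting, Ldha, which codes for the muscle-type lactate dehydrogenase subunit, fell by 1.07 on day 3 (SE 0.11, adjusted p = 1.03e-07) and by 1.12 on day 11 (SE 0.11, adjusted p = 3.48e-08) from 12.49 in control. Bcl2, a gene against apoptosis, rose by 1.05 on day 3 (SE 0.14, adjusted p = 4.88e-06), 1.71 on day 5 and 1.12 on day 11 (adjusted p = 1.51e-06), and did not pass on day 1 (-0.17). Hif1a rose by 0.51 on day 3 (adjusted p = 0.0276) and 0.88 on day 11 (SE 0.17, adjusted p = 2.97e-04). Cdkn1b, a gene that holds cells in G1, rose by 0.63, 1.09 and 0.76 on days 3, 7 and 11, while Ccnd1 fell by 0.82 on days 3 and 11 (0.0014 for both adjusted p). The autophagy genes Sqstm1 and Map1lc3b fell on day 1 (-0.43, adjusted p = 0.0142; -0.39, adjusted p = 0.0492) and rose on day 11 (1.22 and 1.05). The day 1 call of Sqstm1 was lost without control replicate 1 or 2 (adjusted p = 0.0517 and 0.0646). That of Map1lc3b was lost without control replicates 1, 2 or 3 or day 1 replicates 2 or 3 (adjusted p = 0.109, 0.160, 0.117, 0.0774 and 0.129). After cyclic loess both were lost (adjusted p = 0.311 and 0.319), and Map1lc3b also with arrays centred (adjusted p = 0.0508). Txnip was above control on day 7 (0.75, adjusted p = 0.0101) and not different on day 11 (-0.02). Slc16a1 rose on days 3 and 4 only (0.41 and 0.36) and Hk2 on days 3, 4, 5 and 7 (0.43, 0.46, 0.79 and 0.49). Slc2a1 rose on day 1 (0.56, adjusted p = 0.0358; 0.0733, 0.157, 0.0796 and 0.0968 without control replicates 1, 2, 3 or day 1 replicate 3) and fell on day 4 (-0.48). The lactate exporter gene Slc16a3, Ldhb and the AMPK subunit gene Prkaa1 passed on no day, and neither Bax, which the annotation table does not name, nor Cdkn1a, which shares its probe set with another gene, was tested.

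Few genes passed in 1 direction on all 7 days, of which day 1 had only 960 calls. On all days from 3 to 11, 1334 genes lay higher and 1079 lower than control. Higher than control on all 7 days were 112 genes, with AU018091 (smallest change 1.35), Cpt1a (1.22), Sox4 (1.08), Bcl6 (0.92) and Slco5a1 (0.86) having the largest smallest change. Lower on all 7 days were 110 genes, among them Ccl20 (-1.35 at least), Cks2 (-1.23), Cdkn3 (-1.02), H1f5 (-0.98) and Cenpl (-0.94). H1f5 did not pass on day 1 without control replicate 1, 2 or 3 (adjusted p = 0.0759, 0.0635 and 0.0542). Days 3 and 11 shared 1697 higher and 1733 lower genes (348 and 325 from independent lists), and their log2 changes correlated at 0.78 (0.49 simulated with shared controls), with a covariance of 0.2205 (0.0158 simulated). Days 1 and 11 shared 151 higher and 171 lower genes (64.3 and 59.0 from independent lists) with a correlation of 0.10 (0.50 simulated). Their covariance was 0.0172 against 0.0159 simulated. The simulation gave all groups the same spread, whereas median correlations with the own group were 0.992 to 0.994 for control arrays and 0.943 to 0.969 for day 1 arrays. The simulated value may therefore be too large, and the part of the shared controls cannot be told from it.

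A further set of genes was called in opposite directions on days 1 and 11: 135 lower then higher (70.5 from independent lists) and 63 higher then lower (53.8 from independent lists). The copper carrier gene Cp fell by 2.43 on day 1 and rose by 3.39 on day 11, and the siderophore-binding gene Lcn2 fell by 1.67 and rose by 2.54 (SE 0.18). Lbp fell by 0.97 on day 1 (adjusted p = 0.0021) before its rise, while Cdh17 (1.75, then -1.54 with adjusted p = 5.54e-07) and the cytokine gene Il24 (1.22, then -1.56) rose and later fell. Tested directly, day 11 against day 1 gave 5.82 for Cp, 4.20 for Lcn2 and -3.30 for Cdh17, 6234 genes in all (3330 higher, 2904 lower, limma, n = 3 and 3). This comparison was added after the values had been seen. Without day 1 replicate 1, all 135 genes still lay below control on day 1 and 89 were still called. Their median change went from -0.62 (quartiles -0.82 and -0.51) to -0.49 (quartiles -0.70 and -0.38).

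From day 1 to day 3, 5440 genes passed (2703 higher, 2737 lower; 1844 and 3435 with arrays centred on their medians), and 2698 with only the 6 arrays compared. In this step Tnnc1 rose by 5.04 (SE 0.22, 32.9-fold, adjusted p = 1.89e-13) and Cp by 4.94 (SE 0.19, 30.8-fold), while Il24 (-3.17) and H2ac4 (-3.13) fell. From day 3 to day 4 Ogn (2.01, SE 0.23, adjusted p = 3.51e-05) and the early-response gene Fos (1.80) rose and the spindle genes Knstrn (-1.53) and Bub1 (-1.49) fell, among 262 genes (117 higher, 145 lower; 190 and 77 with arrays centred). Each of the 6 arrays, left out in turn, lowered that count: 124, 124 and 164 without day 3 replicates 1, 2 and 3, and 130, 98 and 157 without those of day 4. It was 1018 without day 1 replicate 1, which adds to the variance shared by all comparisons, and 1719 (987 higher, 732 lower) without the 3 arrays that stood apart. From day 4 to day 5 the gelatinase gene Mmp9 rose by 2.17 (SE 0.24, adjusted p = 9.02e-06), as did Usp17ld (2.54, adjusted p = 0.0022), and H2bc8 (-2.05) and the heme oxygenase gene Hmox1 (-1.97, adjusted p = 0.0029) fell, among 2461 genes. That step had 1806 higher and 655 lower (1699 and 1371 after cyclic loess, 1049 and 762 with arrays centred), and 1519, 1504 and 1568 genes without day 4 replicates 2 and 3 and day 5 replicate 3, but 4458 without day 1 replicate 1 and 5191 without the 3 arrays.

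From day 5 to day 7 the stromelysin gene Mmp3 fell by 2.83 (SE 0.20, adjusted p = 2.86e-08) and Ccnb2 by 2.18, while the clock gene Ciart (1.84, adjusted p = 0.0026) and Snord47 (1.66) rose, among 1036 genes (432 higher, 604 lower; 470 and 357 with arrays centred). Without day 5 replicates 2 or 3 the count was 564 or 604, and without day 7 replicates 1, 2 or 3 it was 534, 681 or 461, but 2996 without day 1 replicate 1 and 3731 without the 3 arrays that stood apart. From day 7 to day 9, 205 genes rose and 745 fell (950 in all; 223 and 173 after cyclic loess, 191 and 225 with arrays centred), and those with the largest changes were small RNA genes: Mir680-1 (2.43) and Mir680-2 (2.35) up, Rny3 (-2.43) and Snord33 (-1.95, adjusted p = 0.0049) down. That count was 11, 21 or 338 without day 7 replicates 1, 2 or 3 and 4262, 13 or 9 without day 9 replicates 1, 2 or 3, and limma called 0 with only the 6 arrays compared (4621 at an unadjusted p under 0.05). Without day 1 replicate 1 it was 2842. Snord33 was not called without day 7 replicate 1 or day 9 replicates 2 or 3 (adjusted p = 0.0576, 0.0695 and 0.0594). From day 9 to day 11 only 9 genes passed (2 higher, 7 lower; 3 and 6 after cyclic loess), with Ier2 (1.42, adjusted p = 0.0308) and Snord22 (1.31, adjusted p = 0.0068) up and Mir680-2 (-2.26) and Mir680-1 (-2.20, adjusted p = 7.46e-04) down. It was 346, 4 or 4 without day 9 replicates 1, 2 or 3 and 5, 3 or 4 without day 11 replicates 1, 2 or 3, and limma called 0 with only the 6 arrays compared (1494 at an unadjusted p under 0.05). Without day 1 replicate 1 it was 43. Mir680-1 and Mir680-2 thus rose into day 9 and fell out of it, so their changes rest on the day 9 arrays. They are copies of the same family and may not be separate results. Whether small RNA was recovered alike on all arrays was not tested. Ier2 was lost without day 9 replicates 2 or 3 (adjusted p = 0.420 and 0.355) or day 11 replicates 1, 2 or 3 (adjusted p = 0.0697, 0.223 and 0.192). Snord22 was lost without day 9 replicates 2 or 3 (adjusted p = 0.0743 and 0.132) or day 11 replicates 2 or 3 (adjusted p = 0.0577 and 0.0662). Day 9 replicate 1 resembled day 7 more than its own group: on an axis from the day 7 mean (0) to the day 11 mean (1) it lay at 0.31, and day 9 replicates 2 and 3 lay at 1.01 and 0.93.

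**Figure D4:**
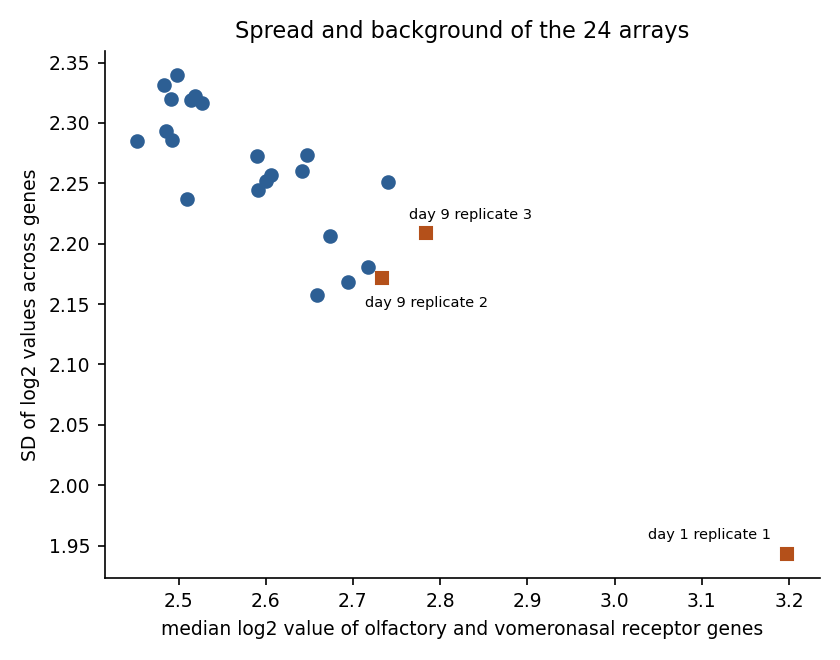
Each of 24 arrays by the median of olfactory and vomeronasal receptor genes (x, log2) and the SD of values across genes (y, log2), squares being day 1 replicate 1 and day 9 replicates 2 and 3. Day 1 replicate 1 lay at 3.20 and 1.94.

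Over the 7 treated days together, 8935 genes (44.8%) differed between days (limma F test, n = 3 a day). A linear trend, the slope of a straight line, was called in 4071 genes, 2137 upward and 1934 downward (2540 and 1229 with arrays centred). The slope test took the 3 arrays of a day as independent points, although they share that day's departure from the line. Its p-values can thus be too small, and a called slope need not be a steady change. The steepest rises per day were those of Fetub (0.54, SE 0.06, adjusted p = 2.89e-07), Lbp (0.46), Cp (0.41, adjusted p = 0.0018), Ogn (0.39) and Rtp4 (0.36), and the steepest falls those of Ccna2 (-0.46, SE 0.04, adjusted p = 9.11e-08), Ccnb2 (-0.45), Bub1 (-0.42), Mki67 (-0.41) and Kif2c (-0.40). Cp rose mostly in 1 step, from a mean of 5.65 on day 1 to 10.51 to 10.66 in the day 3 arrays, and lay at 11.47 on day 11. The slope of Cp thus rests mostly on day 1. Fetub did not rise at every step, with means of 8.69 on day 4 and 8.19 on day 5. The falls were not steady either. Ccna2 lay at 6.66 to 6.76 in the day 4 arrays and higher, at 7.26 to 8.03, in the day 5 arrays. The median change of the mitosis list from control was -3.03 on day 4, -1.99 on day 5 and -3.38 on day 7. Division genes thus lay closer to control on day 5 than on day 4, although still below it. The lists were tested against control only, not between days. Neither the F test nor the slope compares a treated day with control.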

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

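The tests of single arrays for compressed signal, raised background and another day, and the comparison of day 11 with day 1, were chosen after the results had been seen; the tests of control error, of day 1 replicate 1 and of the day 7 axis were written before their values were computed.

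Genes called in opposite directions on days 1 and 11 numbered 198, with Cp at 5.82, Lcn2 at 4.20, Sqstm1 at 1.66, Map1lc3b at 1.44 and Cdh17 at -3.30 for day 11 minus day 1. An error in the control arrays cannot be told apart from a change of the cells, because 100% of the 135 genes that went from lower to higher passed a direct test of the 2 days, an outcome that choosing them for opposite changes had fixed. Day 1 replicate 1 may account for part of the day 1 falls: without it all 135 still lay below control and 65.9% (89 genes) still passed, a share between those set beforehand for either answer, so its part cannot be told apart from a change of the cells. In the 46 genes whose call ended the median change shrank from -0.55 (SE 0.139) to -0.34 (SE 0.116). The SE shrank in the 89 genes still called as well, from 0.141 to 0.126. Choosing the 46 genes for a lost call favoured a smaller change, so these values do not tell why the calls ended. A first fall and a later rise of secreted acute-phase genes could also be a response to fresh medium followed by one to crowding or starvation, which a control sampled on every day would test.

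Day 1 replicate 1 and day 9 replicates 2 and 3 had the highest array medians (4.75, 4.70 and 4.64, next 4.62). Only day 1 replicate 1 lay outside the 21 others in SD across genes (1.94 against 2.16 to 2.34). Day 9 replicates 2 and 3 lay inside (2.17 and 2.21) and correlated with each other at 0.9952. Compressed signal on all 3 would give correlations below -0.3 between the difference from same-day arrays and level, and they were -0.61, -0.39 and -0.1975. This explanation cannot be told apart for all 3, because the outcome for day 9 replicate 3 rests on the definition, 1 of 3 computed, the others giving -0.61, -0.43 and -0.36 with the other arrays of the 3 left out of the reference and -0.54, -0.39 and -0.33 with the level taken as the average of the pair. For day 1 replicate 1 and day 9 replicate 2 all 3 definitions lay below -0.3. Raised background cannot be told apart either: receptor genes lay above all 21 other arrays on 2 of the 3 (3.20 and 2.78, highest other 2.74, SD 0.09) and just under on day 9 replicate 2 (2.73), while another day is unlikely for day 1 replicate 1, which correlated best with a day 1 array by 0.0052. Day 9 replicate 1 correlated best with a day 7 array (difference -0.0181 among the brighter genes). It lay at 0.3083 on the axis from day 7 to day 11, outside the day 7 arrays (-0.03 to 0.06). That test cannot settle whether it is a day 7 array. The axis genes were chosen with all 3 day 7 arrays, which draws those arrays toward 0. A sample from another time cannot be told apart from a late-changing day 9 culture either.

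Probe sets without a gene in the annotation table passed on day 11 in 1319 of 12147 cases (10.9%, 718 higher), against 23.9% of those with 1 gene, and were not analysed further.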

How the results depend on the processing

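Omission of the 3 arrays that stood apart, or of day 1 replicate 1 from every fit, was chosen after the results had been seen, and the cause was not tested for any change given here. Of 1331 values of named genes under alternatives other than leaving out 1 array, 1267 stayed the same, 41 became weaker, 8 stronger and 15 changed sign. Array weights raised the counts to day 1 8640, day 3 8435, day 4 8753, day 7 9140, day 9 11705, day 11 8337, day 3 against 1 10894, day 4 against 3 2334, day 5 against 4 4776, day 7 against 5 3534, day 9 against 7 10744, day 11 against 9 6343, all treated days 17803 and trend 12011. With a 2-fold minimum the counts were day 1 79, day 3 1189, day 4 1361, day 5 1219, day 7 1280, day 9 1301, day 11 1285, day 3 against 1 1294, day 4 against 3 60, day 5 against 4 151, day 7 against 5 160, day 9 against 7 40, all treated days 2942 and trend 1028. At an adjusted p below 0.01 they were day 1 322, day 4 against 3 109, day 5 against 4 1143, day 7 against 5 432, day 9 against 7 19, day 11 against 9 5 and trend 2281. With only the 6 arrays compared, day 1 had 6 genes (1863 at an unadjusted p under 0.05), day 7 7824, day 3 against 1 2698 and day 4 against 3 806, while day 9 against 7 and day 11 against 9 had 0 in limma (4621 and 1494 at an unadjusted p under 0.05). Cyclic loess gave 1528 on day 1 and 396 for day 9 against 7, median centring 416 for day 9 against 7, and omission of the 40% dimmest genes 396 for day 4 against 3 and 1592 for day 9 against 7. Without the 3 arrays the counts were day 1 1544, day 4 against 3 1719, day 5 against 4 5191, day 7 against 5 3731, day 9 against 7 4 and day 11 against 9 183, the last 2 of which rest on day 9 replicate 1 as the only array of its day. The median change of day 3 against 1 became 0.11. Without day 1 replicate 1 in any fit they were day 3 6795, day 4 6789, day 5 7197, day 7 6565, day 9 6922, day 11 6369, day 4 against 3 1018, day 5 against 4 4458, day 7 against 5 2996, day 9 against 7 2842 and day 11 against 9 43. The 105 list calls became 28 with an estimated correlation. A replicate block gave 943 on day 1 and 5112 on day 11, within 1.5-fold as for all other results.

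Leaving out 1 array of the groups compared at a time gave 411 to 3026 on day 1, 4278 to 4606 on day 3, 4593 to 4718 on day 4, 4468 to 5161 on day 5, 4184 to 4473 on day 7, 4495 to 5955 on day 9 and 4316 to 4522 on day 11. Steps ranged, again over the arrays of the 2 days compared, from 4670 to 6778 (day 3 against 1), 98 to 164 (day 4 against 3), 1504 to 2229 (day 5 against 4), 461 to 1143 (day 7 against 5), 9 to 4262 (day 9 against 7) and 3 to 346 (day 11 against 9), all treated days from 8227 to 11287, trend from 3229 to 4480 and list calls from 96 to 107. Of arrays outside the groups compared only day 1 replicate 1 was left out alone, and the counts without it lay above these ranges for each day from 3 to 11 and for days 4 against 3, 5 against 4 and 7 against 5.

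Signs that changed belonged to genes not called on the deposited values with equal weights. After cyclic loess Ldhb became 0.040 and Slc2a1 -0.062 on day 11, and on day 1 Hk2 became 0.088, Cdkn1b 0.044, Ccnd1 0.114 and Prkaa1 0.042. Median centring gave 0.027 for Slc16a1, 0.029 for Ldhb and 0.030 for Txnip on day 11. Array weights gave 0.038 for Ldhb and 0.149 for Txnip on day 11, and 0.176 for Hk2 (adjusted p = 0.0355) and 0.109 for Prkaa1 on day 1. Without the 3 arrays Hk2 became 0.022 and Prkaa1 0.274 on day 1. With 1 array left out, values on day 11 ran from -0.105 to 0.10 for Ldhb, -0.188 to 0.245 for Txnip, -0.058 (and -0.055) to 0.058 for Slc2a1, -0.059 to 0.001 for Slc16a1 and -0.291 to 0.030 for Slc16a3. On day 1 they ran from -0.084 to 0.083 for Hk2 (0.022 and 0.012 without day 1 replicates 1 and 2), -0.076 to 0.004 for Cdkn1b and -0.321 to 0.274 for Prkaa1.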

Other observations

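The 8 gene families were chosen after the results had been seen, as were the splits of 6 arrays, while the tests of the interferon genes were written before their values were computed. The p-values of the families only describe these data.

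Beyond the fixed lists, histone genes fell on day 11 (17 of 26 lower, 3 higher, median -1.32, adjusted p = 3.35e-09, 0.0142 with an estimated correlation), with H2ac4 (-4.39) and H1f5 (-3.67) lowest, while H1f2 rose by 2.20. Near-identical histone copies make the single genes uncertain. Mitochondrial ribosomal protein genes stood at 1 higher and 33 lower of 77 (median -0.25; Mrpl18 -1.43, Mrpl34 -1.40; adjusted p = 7.45e-07, and adjusted p = 0.0951 with an estimated correlation). Cytosolic ribosomal protein genes stood at 23 higher and 2 lower of 61 (median 0.24, adjusted p = 5.31e-05, and adjusted p = 0.267 with an estimated correlation), proteasome genes at 2 and 11 of 39 (adjusted p = 0.0163, and adjusted p = 0.451 with an estimated correlation) and tRNA synthetases at 3 and 5 of 18 (adjusted p = 0.929).

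Circadian clock genes rose on day 11 in 12 of 16 cases (median 0.69; Nr1d2 1.17, Nfil3 1.16, Per1 0.93; adjusted p = 1.51e-07, 0.0075 with an estimated correlation) and on day 5 in 13 with 1 lower (Nr1d1 1.58, Dbp 1.27; Ciart -0.98). Antigen processing and MHC class I genes stood at 12 higher and 2 lower of 31 (H2-T24 2.78, Psmb8 1.54, Tap2 1.39; Nlrc5 -0.55; adjusted p = 1.23e-05, 0.0161 with an estimated correlation). This family and the fixed interferon list were both written with B2m, Tap1, Psmb8 and Psmb9, so they are not separate results. Acute-phase and innate secreted genes fell on day 1 in 8 of 17 cases (median -0.47) and rose on day 11 in 9 (median 0.48; C1s1 2.24, Slpi 1.72, Clu 1.58), and no p is given since they were picked in part for this pattern.

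The interferon response genes that rose by day 11 may mark a response of the tumour cells themselves. Leukocytes among the cells would raise their markers, whose median change was -0.0012, with Cd68 (7.05 against 7.32 in control) and Tyrobp (4.19 against 4.09) the brightest, which argues against them. A shift in array scaling was predicted to end the call, and the list was still called under 2 other scalings (camera, higher adjusted p = 3.11e-12). That outcome could hardly differ, because camera compares the list with all other genes and a shift common to all genes moves both. The median change of all genes on day 11 was -0.03 against 1.51 for the list, which argues against a common shift alone. Treated and untreated cells cultured for equal times, with interferon receptor blocked in some, would separate lactic acid, time and secreted interferon.

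Lower transcript levels of division and sterol synthesis genes and higher levels of Bcl2, chaperone and lysosome genes are in line with a quiescent, stress-adapted state in which tumour cells outlast low glucose. Divisions were not counted, and the chaperone and lysosome calls were lost with an estimated correlation (adjusted p = 0.155 and 0.177). Of 100 random assignments of single treated arrays to days, 1, the real one, reached the 8935 genes of the F test (highest other 933). Again 1 of 100 reached the 4071 genes of the slope (highest other 1206). Arrays of 1 day thus resembled each other more than random sets did, which a culture shared by the 3 arrays would also give. Whole days were not shuffled, so these counts give no support to a linear trend. Whether lactic acid drives such a quiescent state could be tested with equal culture times without lactic acid and with lactate at neutral pH, counting divisions and survival after Bcl2 inhibition. For each comparison of 3 with 3 arrays only 1 of 10 splits, the real one, called as many genes, and 10 are too few for a share under 0.05. The highest other split called 0 against 960 on day 1, 5239 on day 3, 5369 on day 4, 5477 on day 5, 5074 on day 7, 5143 on day 11 and 262 for day 4 against 3. It called 2 against 5414 on day 9, 1033 against 5440 for day 3 against 1, 1 against 2461 for day 5 against 4, 7 against 1036 for day 7 against 5, 516 against 950 for day 9 against 7 and 2 against 9 for day 11 against 9.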
